A study of Drosophila melanogaster with 3 samples.

How the data were processed

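Mabi (CG15479) was measured by chromatin immunoprecipitation and sequencing in whole Drosophila melanogaster embryos of mixed sex aged 0 to 4 h. Per the labels, the line stably expressed Mabi with green fluorescent protein (GFP) at its C-terminus, the antibody was against GFP, and chromatin was sonicated to fragments of 200 to 800 bp. The antibody field of the labels names CG15479, and the description beside it names anti-GFP. The 3 biological replicates formed 1 group, and the labels gave no second condition, so no test between groups was made. The embryos span several stages, and values are means over all their cells.

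The authors deposited 5 peak lists on dm6, in which each peak has a signal value whose scale is not stated, a −log10 q value and a summit. Per the text files deposited with them, each replicate's peaks were derived from its own alignment and a control file, which was the same for all 3. Agreement between replicates can therefore partly be shared with the control. Per the same files, the pooled list was derived from the 3 alignments and the control, and the optimal irreproducible discovery rate (IDR) list from the replicate and pooled lists. The peak caller, aligner and their settings are not given in the sources used here. The alignments, control and signal tracks were not analysed here. The replicate and pooled lists held exactly 30000 peaks each, in 29586, 29607, 29043 and 29082 distinct intervals for replicates 1 to 3 and the pool. Their median widths were 490, 464, 544 and 496 bp, and they covered 9.23%, 8.97%, 9.70% and 9.25% of the chromosome arms. The IDR list held 5049 peaks in 4447 intervals, and every one had the same deposited −log10 q value of 4.16, so that only signal ranked them. Deposited signal values were used only within a list. Read depth is unknown here, so the precision of counts was taken from Wilson intervals over peaks or genes, or exact Poisson intervals for densities. These intervals take peaks or genes as independent and do not measure the spread between replicates.

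Gene models came from Ensembl release 115 and sequence from the RefSeq copy of genome Release 6, which is dm6, and no peak passed a chromosome end. These need not be the copies used by the authors. The replicates were compared by the share of the 5049 strongest peaks of 1 list that overlapped such a peak of another by at least 50% of either peak. The background was 1000 circular shifts of the peaks within each chromosome, in a one-sided permutation test. Each IDR peak was also counted as matched in 0 to 3 replicates by the same overlap. Summits were assigned in order to promoters (within 500 bp of a protein-coding TSS), 5′ UTRs, coding exons, 3′ UTRs, introns, genes without a protein product and intergenic sequence. Their shares were compared with 1000 circular shifts in a two-sided permutation test. Densities on 7 chromosome arms were compared, each with the others together, by two-sided exact binomial tests on arm length. The median signal of promoter and other peaks was compared with 100000 permutations over peaks, and the shares of promoters in the 1263 strongest and 1262 weakest peaks by Fisher's exact test. Peaks at Mabi were taken within 1000 bp of its gene model, with no test.

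A gene had a promoter peak if an IDR summit lay within 1000 bp of any of its annotated TSSs. The 27 gene lists covered early patterning (gap and terminal, pair-rule, segment polarity, Hox, dorsoventral, cellularisation and early zygotic), maternal-effect, cell death, cell cycle, Polycomb and trithorax, insulator and GAGA-type factor, and heat shock genes. They further covered late neuronal, muscle, antimicrobial peptide, E(spl) complex, ribosomal protein, mitochondrial ribosomal protein, proteasome, histone, chemoreceptor, cuticle, chorion, Jonah protease, accessory gland, tRNA and snRNA genes. Protein-coding lists were tested against the other protein-coding genes, of 13968, and tRNA and snRNA genes against all other annotated genes, of 18277, by two-sided Fisher's exact tests. The lists were written before the data were examined. After the peak files were opened and before any list was tested, 2 symbols were respelled, 1 duplicate was dropped, and the chorion pattern was narrowed so that Cp190 and Cp110 did not match it. Motifs were 23 consensus sequences, counted on either strand in windows reaching 100 bp to either side of IDR summits and at positions 1000 bp to the lower-coordinate side, and compared by two-sided exact McNemar tests. Each family of tests was adjusted by Benjamini-Hochberg, with a threshold of 0.05 on the adjusted value.

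Genes were named by a rule fixed before the data were examined. It took Mabi, the genes nearest the 10 strongest IDR peaks, up to 3 members of each list with the highest promoter signal, and all members with a peak where these were 5 or fewer. Up to 2 members without a promoter peak, in alphabetical order, were named from lists in which more than 50% of members had one. The alternatives fixed at the same time were other overlaps, promoter widths, TSS distances and motif windows, the higher-coordinate flank, and windows shuffled with dinucleotide counts kept. They also included the strongest 2524 of the IDR peaks, 10000 random lists matched on gene length in 5 bins and number of TSSs, and leaving out each replicate. In the matching, all genes with 3 or more TSSs formed 1 class. Leaving out a replicate kept the IDR peaks that both others matched (4072, 3855 and 3864 peaks without replicates 1, 2 and 3), and IDR itself was not recomputed. Chosen after seeing the data were the 24951 lower-ranked pooled peaks as background, genes with a pooled peak of any rank, the outermost TSS of each gene, 1 summit per interval, and arms without the Y.

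The code was tested on simulated data. With 70.2% of peaks kept in a simulated second list, 73.4% were found in common. Sets of shifted summits gave 0 feature calls in 70 tests, and uniform summits gave 1 arm call in 70. All 10 planted lists of 20 genes, 60% of them given a peak, were called, and 0 of 40 other lists. A motif planted in 5% of windows was called, and 0 of 22 others. Adding 100 to the signal of simulated promoter peaks gave a difference of medians of 111 (permutation p = 0.000500, the smallest possible there). Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.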

Results

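Binding of the Drosophila melanogaster protein Mabi (CG15479, mabiki, known for a role in cell death in the early embryo) was mapped by chromatin immunoprecipitation and sequencing in whole embryos aged 0 to 4 h. The embryos came from a transgenic line, per the labels, that carries Mabi with green fluorescent protein (GFP) at its C-terminus, and an anti-GFP antibody was used. The series held 1 group of 3 biological replicates of mixed sex and no second condition, so no groups were compared. The comparisons made were between the replicates, between peaks and shifted or neighbouring positions, and between gene groups. Each replicate was represented by a deposited list of 30000 peaks, and the read depth behind each list is unknown here. The pooled replicates gave a further 30000 peaks, and the authors' optimal IDR list (irreproducible discovery rate, a measure of the agreement of replicate ranks) held 5049. These 5049 peaks lay in 4447 distinct intervals, since an interval could hold several summits, and covered 1.48% of the chromosome arms. Their deposited signal values ran from 291 to 8663 with a median of 473, and describe peaks within that list only.

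The strongest IDR peak lay at the tagged gene itself. The Mabi gene model occupies 2L from 13233798 to 13234660 on the minus strand (dm6). The strongest IDR peak spanned 13233953 to 13236013, with its summit at 13235091, 431 bp upstream of the Mabi transcription start site (TSS). The same interval held a further summit at 13235290, which ranked 3 of 5049 with a signal of 5747. In the separate lists, the strongest peak at Mabi ranked 1 in replicate 1, 2 in replicate 2 and 1 in replicate 3. Within each of those lists its signal was 50.6, 50.2 and 70.4 times the list's median. The gene downstream of Mabi's 3′ end, Prosalpha6T, a testis proteasome subunit gene, had a promoter peak with a signal of 752. The next gene, CG16815, had the peak that ranked 9, at 13229159 to 13230146 on 2L, with a signal of 3752. The labels also describe the source as an insertion targeting Mabi. Whether the transgene added copies of this locus, and how many, is not given in the sources used here.

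**Figure D1:**
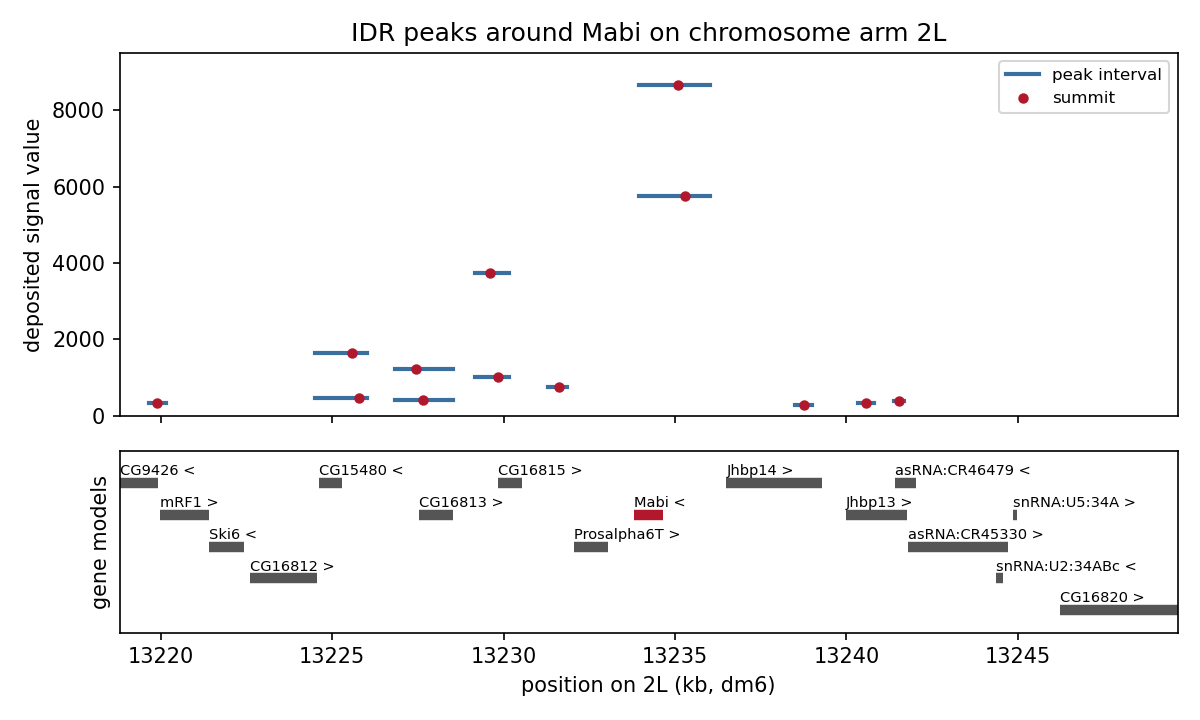
IDR peaks (blue lines, with red points at their summits) by deposited signal value on the vertical axis and position on 2L in kb on the horizontal axis, above the gene models. The peak over the Mabi TSS reached 8663, and the peak at CG16815 reached 3752.

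Apart from the Mabi locus, the strongest peaks included several at genes for transcription factors and signalling regulators. A peak in an intron of Kr-h1, a hormone-response transcription factor gene, had a signal of 6785 (2L, 6088143 to 6088990). Its nearest TSS was shared with CG45075. The peak at hth, which encodes a homeodomain cofactor of Hox proteins, reached 4257 with its summit upstream of a TSS and in its promoter (3R, 10614110 to 10614866). An intronic peak of aop, an ETS-family repressor gene, reached 4130 (2L, 2163530 to 2165749), and a peak 1249 bp upstream of trbl, a regulator of String, reached 4032 (3L, 20402366 to 20403723). Svil (3911), Akap200 (3831) and the pair-rule gene hairy, listed as hry (3716), completed the 10 strongest peaks. All 10 overlapped one of the 5049 strongest peaks in each of the 3 replicates, and their rank within a replicate lay between 1 and 20.

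The 3 replicates placed most of their strong peaks at the same sites. Among the 5049 strongest peaks of each list, replicates 1 and 2 shared 75.2%, replicates 1 and 3 shared 80.0%, and replicates 2 and 3 shared 81.6%. Peaks moved around their chromosomes by random circular shifts shared 1.83% to 2.03% on average (one-sided permutation test with 1000 shifts, p = 0.000999 for each pair, the smallest they can give). Beyond 5049 peaks sharing fell with list depth, and between the complete lists of 30000 peaks it was 58.0% to 65.5%, against 9.90% to 10.7% after shifts. Of the 5049 IDR peaks, 3594 (71.2%, Wilson 95% interval 69.9 to 72.4) were matched by a strong peak in all 3 replicates. A further 1009 were matched in 2 replicates, 431 in 1 and 15 in none. Replicate 1 matched the fewest, at 4209, while replicate 2 matched 4582 and replicate 3 matched 4440. Against the complete lists, 4951 IDR peaks (98.1%) were matched in all 3 replicates. With summits required to lie within 100 bp, only 55.5% were matched in all 3. The IDR list was itself derived from these replicate lists and the pooled list, and was identical in position and signal to the 5049 strongest pooled peaks.

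**Figure D2:**
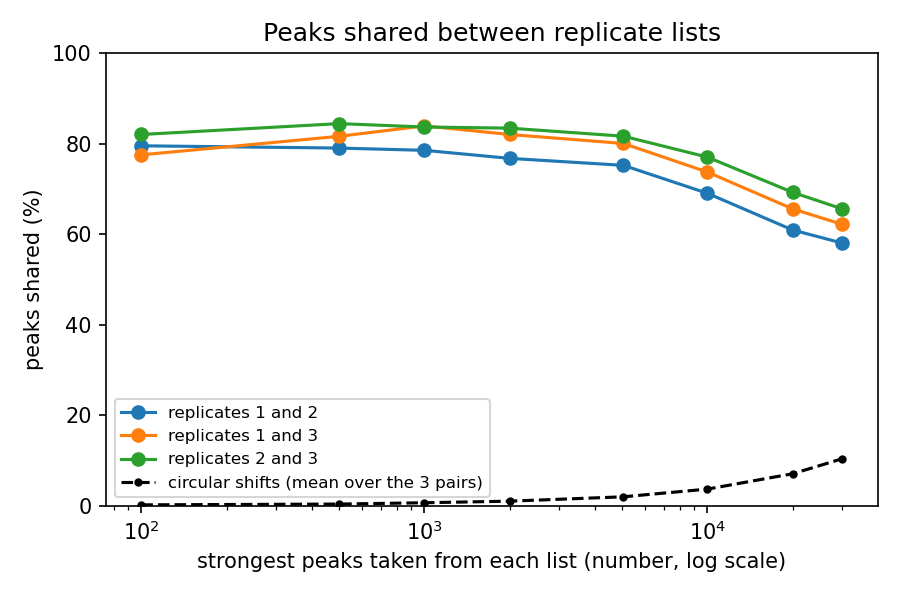
Percent of peaks shared between each pair of replicate lists (vertical axis) by the number of strongest peaks taken from each list (horizontal axis, log scale), with the mean after circular shifts as a dashed line. At 5049 peaks the 3 pairs shared 75.2% to 81.6%.

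Summits were concentrated at promoters and sparse in coding exons and 3′ UTRs. A promoter, taken as within 500 bp of a protein-coding TSS, held 2153 summits (42.6%, Wilson 95% interval 41.3 to 44.0), against 11.5% after circular shifts. Coding exons held 99 summits (1.96% against 13.9%), and 3′ UTRs held 54 (1.07% against 4.48%). Intergenic sequence held 762 (15.1% against 27.9%) and introns 1771 (35.1% against 39.3%). The remaining 5′ UTR sequence held 71 (1.41% against 0.791%). Each of these 6 differences passed the two-sided permutation test (p = 0.0020, the smallest that 1000 shifts can give, and adjusted p = 0.00233). The shares add up to the whole, so the promoter excess by itself lowers the others. The lower intron share is therefore no measure of avoidance of introns. Genes without a protein product held 139 summits (2.75% against 2.10%, adjusted permutation p = 0.0719). That difference passed without replicate 2 (adjusted permutation p = 0.0400) and without replicate 3 (adjusted p = 0.0233). The intron difference was lost when promoters were taken as within 250 bp (ratio 0.97, adjusted permutation p = 0.380), and the 5′ UTR difference when taken as within 1000 bp (ratio 1.04, adjusted p = 0.913), while within 250 bp the 5′ UTR ratio was 2.87 in place of 1.78. The 24951 lower-ranked pooled peaks had 25.8% of their summits in promoters and 11.5% in coding exons, and IDR peaks differed from them in both shares (Fisher's exact test, adjusted p = 1.96e-120 and 3.29e-127). Against those peaks, a comparison chosen after seeing the data, neither introns (ratio 0.969, adjusted exact p = 0.157) nor 5′ UTRs (ratio 1.30, adjusted p = 0.0693) passed. The median distance from an IDR summit to the nearest protein-coding TSS was 856 bp, and 895 summits lay within 100 bp. Of those within 500 bp, 57.2% lay upstream.

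**Figure D3:**
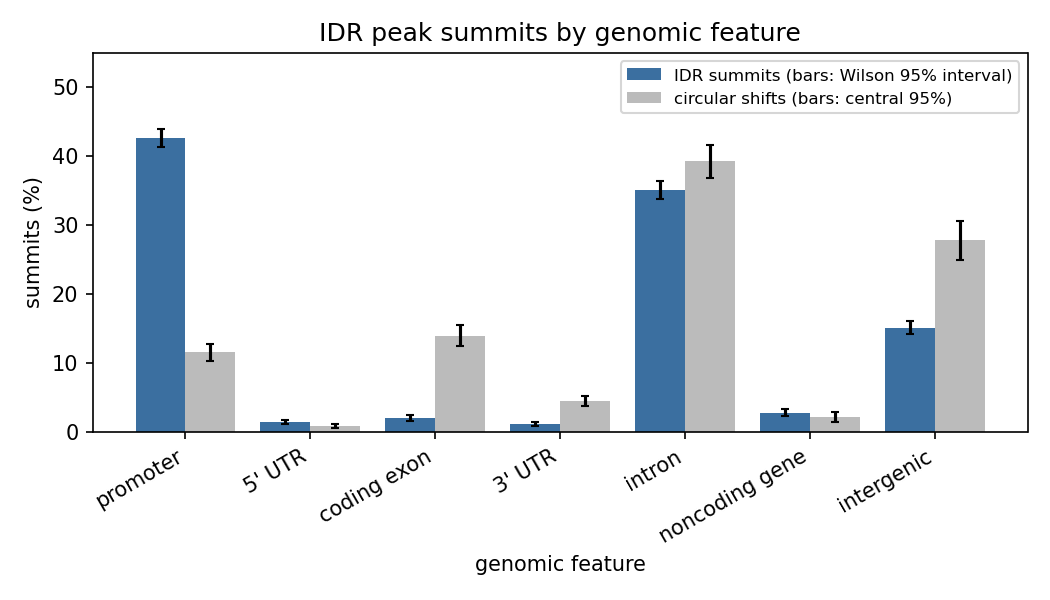
Percent of the 5049 IDR summits in each genomic feature (blue, with Wilson 95% intervals) beside the mean and central 95% of circular shifts (grey). Promoters held 42.6% of summits against 11.5% after shifts.

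The signal of promoter peaks did not differ detectably from that of other peaks. The 2153 promoter peaks had a median signal of 466 and the 2896 others a median of 479, a difference of -13.3 (two-sided permutation test with 100000 resamples, p = 0.154). Promoters made up 39.7% of the 1263 strongest peaks and 41.8% of the 1262 weakest (Fisher's exact test, p = 0.292). Without replicate 1 the difference was -21.4 (permutation p = 0.0518), and without replicate 3 it was -0.227 (permutation p = 0.979).

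The Y chromosome held no IDR peak, and the X held fewer per Mb than the other arms together. The density was 39.6 peaks per Mb on both 2L and 2R, 36.9 on 3L and 38.7 on 3R. It was 34.0 on the X (exact Poisson 95% interval 31.7 to 36.5) and 28.2 on chromosome 4 (19.9 to 38.7). Against the other arms together, the X had a ratio of 0.913 (two-sided exact binomial test, adjusted p = 0.0325). The Y differed too, with 0 peaks in 3667352 bp (adjusted exact p = 8.17e-59), and among the lower-ranked pooled peaks it had 1. The X was lower among those peaks as well (ratio 0.952, adjusted exact p = 0.00637), so its lower density was not particular to IDR peaks. The higher densities on 2L (adjusted exact p = 0.0301), 2R (adjusted p = 0.0279) and 3R (adjusted p = 0.0464) depended on counting the empty Y among the other arms, and none passed without it (adjusted p = 0.168, 0.168 and 0.350). The call for 2L was also lost without replicate 1 (adjusted exact p = 0.0622), 2 (0.0531) or 3 (0.0624), that for 3R without replicate 1 (0.0756) and that for 2R without replicate 3 (0.0539). With the strongest 2524 peaks, 2L and 3R were lost (adjusted exact p = 0.0774 for each) and chromosome 4 passed as lower (ratio 0.523, adjusted p = 0.0295). The test takes peaks as independent, and peaks in clusters make its p-values too small. It uses arm length only. Neither the copies of the X and Y in these embryos of mixed sex nor how well reads map to the Y was allowed for. The lower densities on the X and Y are therefore no measure of weaker binding there.

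Genes of the early segmentation and dorsoventral systems carried promoter peaks far more often than other genes. A promoter peak, meaning an IDR summit within 1000 bp of any TSS, was present at 2566 of 13968 protein-coding genes (18.4%). It was present at 12 of 14 gap and terminal genes, 7 of 9 pair-rule genes, 9 of 13 segment polarity genes and 20 of 29 dorsoventral zygotic genes. The 17 genes of cellularisation and early zygotic transcription had one at 14. Fisher's exact test with Benjamini-Hochberg adjustment over 27 lists gave adjusted p values from 2.19e-08 for the dorsoventral genes to 0.000401 for the pair-rule genes. The shares were 85.7% (Wilson 95% interval 60.1 to 96.0), 77.8% (45.3 to 93.7), 69.2% (42.4 to 87.3), 69.0% (50.8 to 82.7) and 82.4% (59.0 to 93.8). Against random lists matched on gene length and number of TSSs, the ratio for gap and terminal genes was 3.08 in place of 4.68, and that for dorsoventral genes 2.45 in place of 3.78. With the strongest 2524 peaks the ratio was 5.68 for segment polarity genes in place of 3.78, 6.22 for dorsoventral genes and 7.47 for cellularisation and early zygotic genes in place of 4.50. Neighbouring genes can share a peak, so the test's p-values treat as separate some genes that are not.

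Among gap and terminal genes, the terminal gene tll had a promoter peak of 2793 (3R, 30851655 to 30852452), cnc had 1567 and Kr had 697, while ems and kni had none. Among pair-rule genes, hry had 3716, run had 1417 and ftz had 1060, and eve and slp2 had none. The signalling genes hh (1315) and wg (1256) and the T-box gene mid (1053) led the segment polarity genes, whose members en and gsb-n had none. In the dorsoventral list, brk, a repressor of Dpp targets, had 1352, the midline regulator sim had 1325 and zen, a regulator of dorsal fates, had 1224. The members htl and pyr, an FGF receptor gene and an FGF ligand gene, had none. The early zygotic genes esg (2125), Tollo (1892) and 18w (1593) stood above the list's median of 823, and Bro and slam had none.

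Chromatin regulators and developmental gene complexes also exceeded other genes. Promoter peaks were present at 12 of 19 Polycomb and trithorax group genes (adjusted exact p = 6.77e-05), led by trx (2003), Sfmbt (1730) and ph-p (1191), and were not listed for ash2 and esc. They were present at 10 of 15 insulator and GAGA-type factor genes (adjusted exact p = 0.000157), led by pita (1272), Chro (1242) and Cp190 (821), and were not listed for BEAF-32 and CTCF. The E(spl) complex, whose genes respond to Notch signalling, had them at 8 of 11 genes (adjusted exact p = 0.000306), led by E(spl)m7-HLH (1768), E(spl)malpha-BFM (1194) and E(spl)m2-BFM (564). E(spl)m2-BFM kept 0 promoter summits without replicate 2 or replicate 3. E(spl)m6-BFM and E(spl)mbeta-HLH had none. Of the 8 Hox genes, 6 had one (adjusted exact p = 0.00158), led by Dfd (701), Antp (582) and lab (553), and abd-A and pb had none. The Hox call was lost against random lists matched on gene length and number of TSSs (ratio 2.02 in place of 4.09, adjusted permutation p = 0.0899). It was also lost with 1 TSS per gene, a test chosen after seeing the data (ratio 2.26, adjusted exact p = 0.20). With the strongest 2524 peaks the Hox ratio was 6.58 (adjusted exact p = 0.00102). The E(spl) call was lost without replicate 2 (adjusted exact p = 0.0856) and with the strongest 2524 peaks (adjusted p = 0.143). The ratio for Polycomb and trithorax genes was 2.28 against matched random lists in place of 3.45, and that for E(spl) genes 10.5 in place of 3.97.

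Ribosomal protein genes were the remaining group above other genes, and chemoreceptor, cuticle, accessory gland and histone genes lay below. A promoter peak was present at 42 of 93 ribosomal protein genes (45.2%, ratio 2.48, adjusted exact p = 2.19e-08), led by RpL7 (1487), RpL24-like (1458) and RpS25 (1382). Among genes with a pooled peak of any rank, a background chosen after seeing the data, all 10 groups still passed, with ratios from 1.48 for these genes to 2.70 for the cellularisation and early zygotic genes. Only 3 of 179 odorant, gustatory and ionotropic receptor genes had one (adjusted exact p = 9.25e-11), namely Or85f (835), Ir60b (587) and Or88a (376), which kept 0 promoter summits without any 1 of the 3 replicates. The ratio of 0.0902 for this list became 0.230 among genes with a pooled peak of any rank (adjusted exact p = 0.00140), 0.195 within 2000 bp (adjusted p = 2.28e-10) and 0 within 500 bp (adjusted p = 8.26e-12). Only 2 of 117 cuticle protein genes had one (adjusted exact p = 1.15e-07), Cpr73D (1290) and TwdlE (317), and only Sfp26Ad (1107) of 47 accessory gland protein genes (adjusted p = 0.00362). None of 111 replication-dependent histone genes had one (Wilson 95% interval 0 to 3.35%, adjusted exact p = 3.16e-09). No lower-ranked pooled peak lay at a histone gene either. Those genes lie in a tandem repeat, so their absence from the lists is no measure of binding there. The accessory gland call was lost against matched random lists (adjusted permutation p = 0.295) and with the strongest 2524 peaks (adjusted exact p = 0.203). Among genes with a pooled peak of any rank it was also lost (adjusted exact p = 0.311), as was the cuticle call (adjusted p = 0.0603).

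The other lists did not pass the test. Of 23 cell death genes 8 had a promoter peak (adjusted exact p = 0.0942), led by the tagged gene Mabi itself (8663), the caspase inhibitor gene Diap1 (1474) and hid (1391). This list passed without replicate 2 (adjusted exact p = 0.0497) and without replicate 3 (adjusted p = 0.0141), within 500 bp of a TSS (adjusted p = 0.0285) and with the strongest 2524 peaks (adjusted p = 0.0399). It did not pass without replicate 1 (adjusted exact p = 0.125), or among genes with a pooled peak of any rank (ratio 1.17 in place of 1.90, adjusted p = 0.845). Matched random lists gave a ratio of 1.78 (adjusted permutation p = 0.158). The list counts the tagged gene and was not tested without it. Of 35 maternal-effect and germ plasm genes 7 had one (adjusted exact p = 0.858), led by exu (686), cact (476) and vas (464). Of 22 cell cycle genes 7 had one (adjusted exact p = 0.242), with CycE (2037), CycB (716) and E2f1 (572) highest. Of 16 heat shock genes 5 had one (adjusted exact p = 0.262), namely Hsp23 (1684), Hsp83 (764), Hsf (617), and Hsp22 and CG4456, which shared 1 peak of 320 and kept 0 summits without replicate 1 or 3. Of 16 late neuronal genes 3 had one (adjusted exact p = 1), which were elav (1052), Syx1A (947) and Csp (765). Of 16 muscle structural genes 2 had one (adjusted exact p = 0.812), Tm1 (468) and Msp300 (319, with 0 summits left without replicate 2 or 3), and of 14 antimicrobial peptide genes only Def did (556, adjusted p = 0.55).

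Mitochondrial ribosomal protein genes had a promoter peak at 18 of 73 (adjusted exact p = 0.245), led by mRpL16 (1628), mRpS10 (1561) and mRpL40 (804). They passed against matched random lists (ratio 2.73, adjusted permutation p = 0.000675) and with the strongest 2524 peaks (ratio 1.88, adjusted exact p = 0.0485), while among genes with a pooled peak of any rank the direction turned (ratio 0.956, adjusted exact p = 0.926). Proteasome genes had one at 6 of 48 (adjusted exact p = 0.434), with Rpn8 (1200), Rpn2 (1129) and Prosalpha6T (752) highest, the last of these beside Mabi. No chorion or vitelline membrane gene of 14 (adjusted exact p = 0.140) and no Jonah serine protease gene of 16 (adjusted p = 0.0942) had one. Of 290 tRNA genes 42 had one (ratio 0.860 to all other annotated genes, adjusted exact p = 0.391), from 32 distinct intervals. The strongest were at tRNA:iMet-CAT-1-3 (1669) and at tRNA:Ala-TGC-1-1 and tRNA:Ala-TGC-2-1, which shared a peak of 906. Against matched random lists the direction turned, with a ratio of 1.56 (adjusted permutation p = 0.00617), and among genes with a pooled peak of any rank the ratio was 0.611 (adjusted exact p = 0.000501). Of 32 snRNA genes 7 had one (adjusted exact p = 0.55), led by snRNA:U1:21D (436), snRNA:U2:34ABa (422) and snRNA:U4:39B (346). The peak of snRNA:U1:21D was lost without replicate 2 or 3 (0 summits left), and that of snRNA:U4:39B without replicate 1 or 2 (0 left).

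**Figure D4:**
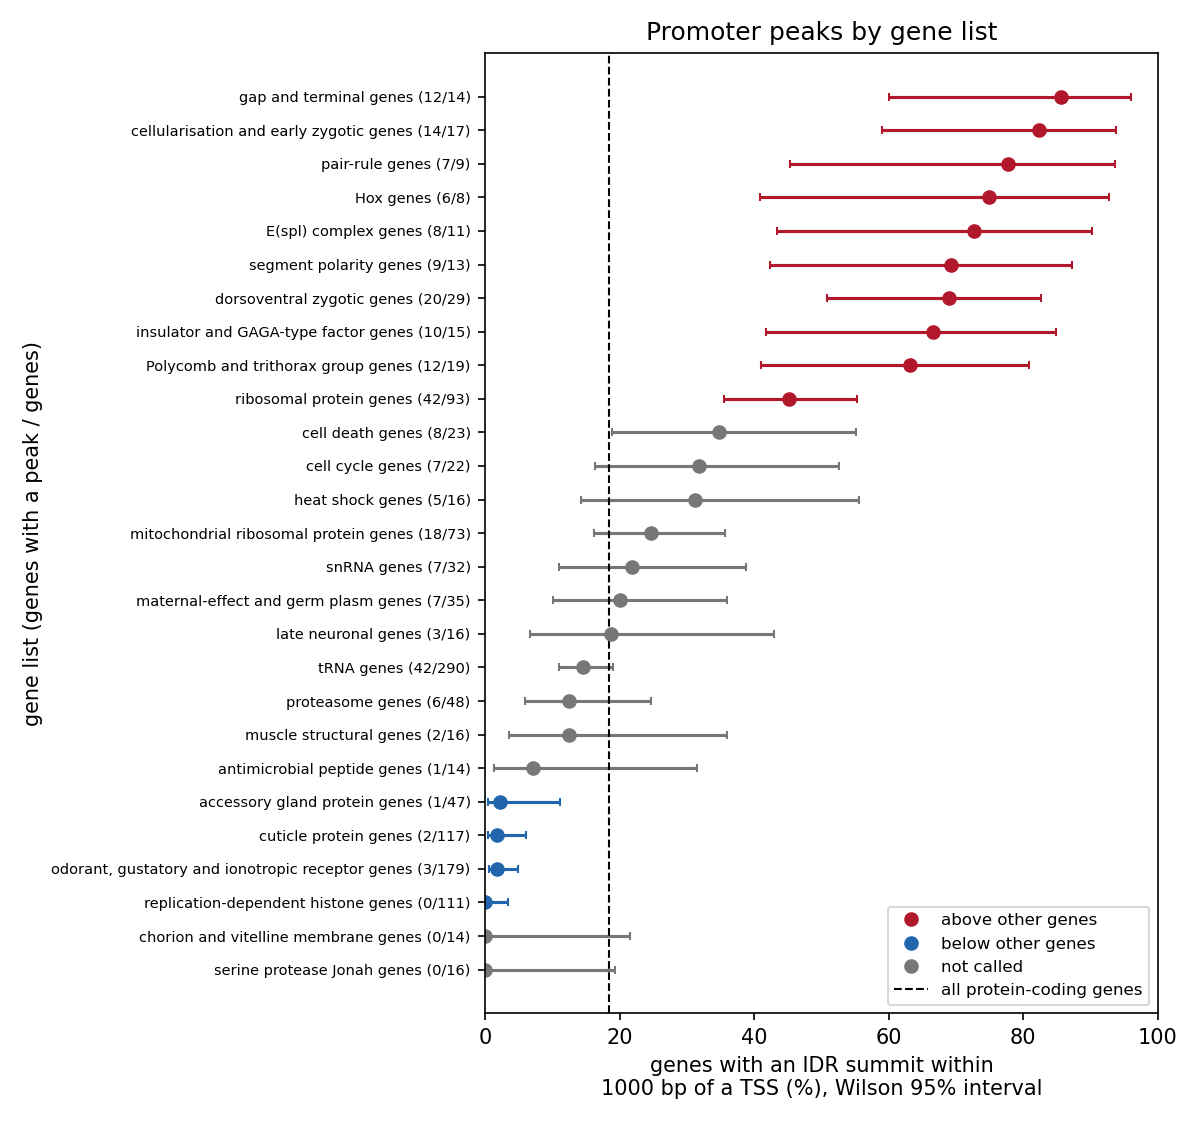
Percent of the genes of each list with an IDR summit within 1000 bp of a TSS (points, with Wilson 95% intervals), coloured by the result of Fisher's exact test, with the share of all protein-coding genes (18.4%) as a dashed line. Gap and terminal genes stood highest at 85.7%, and histone genes at 0.

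Summits were rich in the sequence bound by Zelda, the activator of the early zygotic genome, and in GA and CA repeats. The Zelda consensus CAGGTAR was present in 512 of 5049 windows reaching 100 bp to either side of IDR summits (10.1%, Wilson 95% interval 9.34 to 11.0), against 3.23% of windows 1000 bp away. GAGAGAG, bound by GAGA factor, was present in 11.0% against 3.82%, and CACACAC in 19.1% against 7.35%. The core promoter sequences of DREF (2.08% against 0.654%) and M1BP (1.53% against 0.416%) were also higher, as was Ohler 7 (3.74% against 1.88%). The E-box of Twist and Snail was slightly higher at 25.4% against 22.9% (adjusted p = 0.00678), and the other 6 had adjusted p values of at most 3.66e-08 (two-sided exact McNemar test, adjusted over 23 motifs). The E-box call was lost with windows of 50 bp to either side (adjusted exact p = 0.151) and against lower-ranked pooled peaks, a background chosen after seeing the data (adjusted p = 0.578). Against those peaks the ratio was 1.5 for DREF in place of 3.18 and 1.77 for M1BP in place of 3.67, and both still passed. Promoters held 42.6% of IDR summits and 25.8% of the lower-ranked ones. That difference was not allowed for and could itself give such ratios. Outside promoters, IDR peaks had DREF in 0.518% and M1BP in 0.173% of windows, no more than the windows 1000 bp away, and Ohler 7 in 2.14%. Against summit windows with shuffled bases and kept dinucleotides the ratios were 17.5 for DREF, 7.7 for M1BP, 4.64 for GAGAGAG and 4.42 for CACACAC, and with windows of 50 bp to either side it was 5.9 for DREF.

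Sequences of several patterning and signalling factors were less frequent at summits than 1000 bp away. The homeodomain core TAATTA was present in 8.48% of summit windows against 11.8%, the Caudal consensus in 20.6% against 24.3% and STAT92E in 4.79% against 6.24%. Hunchback (11.7% against 13.2%) and Kruppel (0.139% against 0.416%) were also lower. Against summit windows with shuffled bases and kept dinucleotides, none of these 5 passed as lower. Hunchback (ratio 0.899, adjusted exact p = 0.0589), STAT92E (ratio 0.877, adjusted p = 0.175) and Kruppel (ratio 0.583, adjusted p = 0.376) kept their direction. Caudal (ratio 1.17, adjusted exact p = 0.000226) and the homeodomain core (ratio 1.18, adjusted p = 0.0277) turned direction and passed as higher. Dorsal (ratio 2.05, adjusted exact p = 0.000337), Ohler 6 (ratio 1.91, adjusted p = 0.0298) and Opa (ratio 1.48, adjusted p = 0.0175) also passed as higher against the shuffled windows. So did BEAF-32, present in 10 summit windows and 0 shuffled windows (adjusted exact p = 0.00449). Tailless passed as lower there (adjusted exact p = 0.0456) and against the windows on the higher-coordinate side (adjusted p = 0.0382). Against lower-ranked pooled peaks, Caudal (adjusted exact p = 0.194), STAT92E (adjusted p = 0.661) and Kruppel (ratio 0.516, adjusted p = 0.246) were lost, Hunchback turned to a ratio of 1.06, and Su(Hw) passed as lower (ratio 0.344, adjusted p = 0.00294). The Hunchback call was also lost with windows of 50 bp to either side (adjusted exact p = 0.0556) and with 1 summit per interval (adjusted p = 0.0727). The Kruppel call rested on 7 windows against 21 and was lost without replicate 1 (adjusted exact p = 0.146), 2 (0.153) or 3 (0.153). It was also lost with windows of 50 bp to either side (adjusted exact p = 0.103), on the higher-coordinate side (adjusted p = 0.105) and with the strongest 2524 peaks (adjusted p = 0.195). The sequences of Bicoid, Dorsal, Tailless, BEAF-32, the TATA box, Ohler 6, Su(Hw), CTCF, Grainyhead, Runt and Opa did not pass. Of these, BEAF-32 also passed as higher with the strongest 2524 peaks and without replicate 2 or 3 (adjusted exact p = 0.0412 for each replicate left out), and the TATA box passed as lower with the strongest 2524 peaks (ratio 0.513, adjusted p = 0.0351) and without replicate 2 (adjusted p = 0.0465) or 3 (adjusted p = 0.0436). Mean GC content was 44.6% ± 7.43 (SD over windows) at summits and 42.5% ± 9.40 at the windows 1000 bp away.

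Zelda sequences were more frequent in strong peaks and in peaks outside promoters, and the core promoter sequences were more frequent in promoter peaks. The Zelda consensus was present in 14.3% of the 1263 strongest peaks and 7.05% of the 1262 weakest (Fisher's exact test, adjusted p = 1.10e-07). CACACAC fell from 23.9% to 15.9% (adjusted exact p = 6.75e-06), and GAGAGAG from 13.2% to 9.03% (adjusted p = 0.00560). The homeodomain core rose from 6.41% to 10.2% (adjusted exact p = 0.00407). The Zelda consensus was present in 12.1% of peaks outside promoters and 7.52% of promoter peaks (adjusted exact p = 5.18e-07). DREF was present in 4.18% of promoter peaks and 0.518% of others (adjusted exact p = 3.85e-19), and M1BP in 3.34% and 0.173% (adjusted p = 3.55e-20). Ohler 7 was present in 5.90% and 2.14% (adjusted exact p = 4.52e-11). Also more frequent in promoter peaks were BEAF-32 (0.464% and 0, adjusted exact p = 0.000903), Ohler 6 (1.35% and 0.449%, adjusted p = 0.00300) and the TATA box (1.49% and 0.622%, adjusted p = 0.00799). The homeodomain core (9.61% and 7.63%, adjusted exact p = 0.0361) and CACACAC (20.6% and 18%, adjusted p = 0.0428) were as well, and Bicoid was less frequent (5.25% and 7.15%, adjusted p = 0.0174). Both splits were chosen after seeing the data. Promoters without a peak were not searched for these sequences. The promoter split thus cannot tell a trait of these peaks from one of promoters in general.

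**Figure D5:**
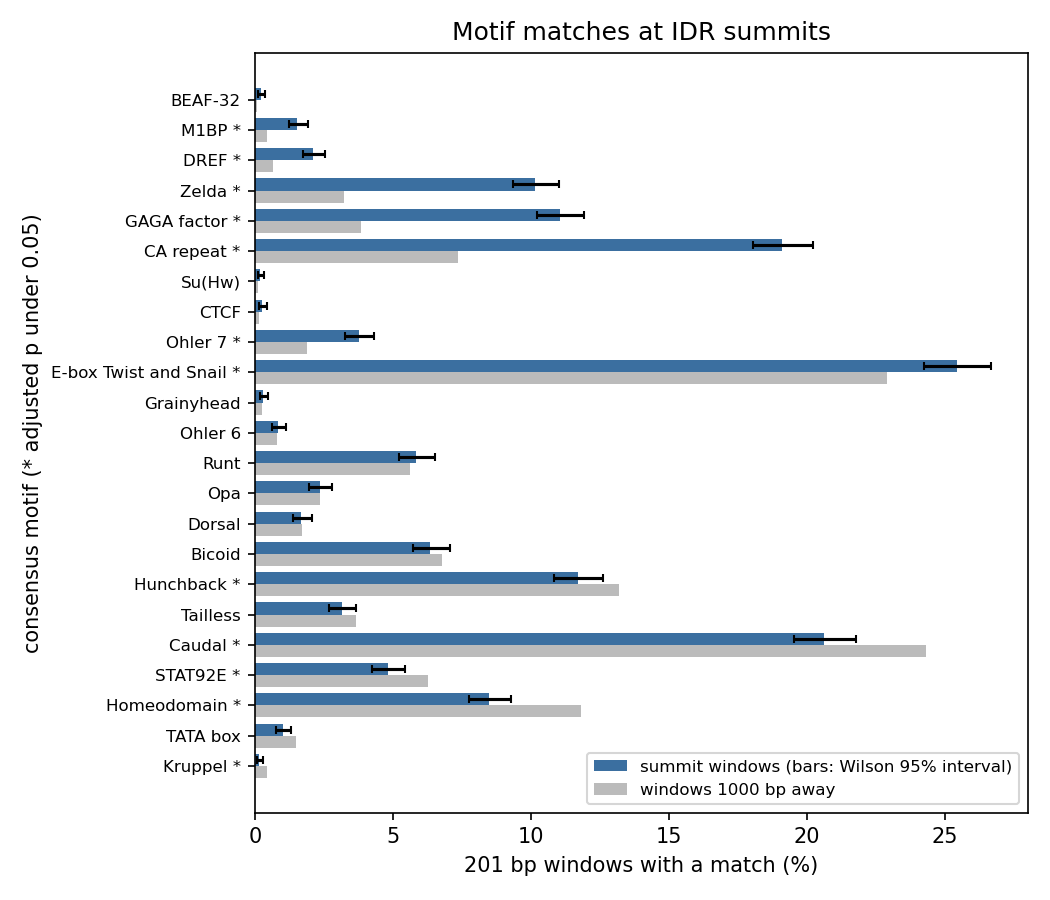
Percent of windows (100 bp to either side) with at least 1 match to each consensus at IDR summits (blue, with Wilson 95% intervals) and 1000 bp to the lower-coordinate side (grey), ordered by their ratio. Stars mark the 12 motifs past the threshold, with CACACAC at 19.1% against 7.35%.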

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

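Chosen only after the data were seen were the comparisons with lower-ranked pooled peaks, genes with a pooled peak of any rank, the outermost TSS, 1 summit per interval and arms without the Y. The other alternatives were fixed before the data were examined. A tested value was taken as kept if its direction and side of the threshold were the same. Counts of calls were taken as kept if their size stayed near the main count, even where the members called had changed. A named gene was kept if any promoter summit was left. On these rules, 53 alternatives for the main values and counts were kept, 7 were weaker, 1 was stronger and 6 moved. For single features, arms, lists, motifs and genes, 799 were kept, 74 were weaker, 19 were stronger and 44 turned direction. The cause was not tested for any of them, except that leaving out a replicate or taking the strongest 2524 leaves fewer peaks. Read depth is unknown here, and its effect was not tested. Among genes with a pooled peak of any rank, histone and chorion genes gave no value, since none was left.

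The share of IDR peaks found in every replicate was 72.7% with at least 1 bp shared, 55.5% with summits within 100 bp, and 97.8% for the strongest 2524 IDR peaks. It was 76.4% to 80.6% without 1 replicate, where matches in only 2 replicates were required. The number of arms past the threshold was 3 to 4 without 1 replicate, against 5, and 1 without the Y chromosome, where the ratio for 3L turned to 0.971.

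The number of lists with fewer promoter peaks was 2 among genes with a pooled peak of any rank, against 4. Ratios of lists that turned direction there were 0.798 for maternal-effect, 1.03 for antimicrobial peptide, 0.956 for mitochondrial ribosomal protein and 0.857 for snRNA genes. Within 2000 bp they were 0.825 for late neuronal and 1.01 for tRNA genes, and for the strongest 2524 peaks 0.60 for maternal-effect and 0 for snRNA genes. Against matched random lists they were 0.770 for maternal-effect, 0.467 for late neuronal, 1.13 for antimicrobial peptide and 1.56 for tRNA genes. With the outermost TSS the ratio for maternal-effect genes was 0.862. Without 1 replicate the ratio was 0.956 to 1.29 for maternal-effect, 0.778 to 1.06 for tRNA and 0.456 to 0.769 for snRNA genes. Of all these, only the tRNA genes against matched lists passed the threshold. Among genes named from the lists for a promoter peak, 11 kept 0 summits within 500 bp and 10 kept 0 with the strongest 2524 peaks. Without replicates 1, 2 and 3, the numbers were 4, 5 and 6.

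The number of motifs lower at summits was 3 with windows of 50 bp to either side, 1 against shuffled windows and 2 against lower-ranked pooled peaks, against 5. The number higher was 13 against shuffled windows, against 7. BEAF-32 gave no ratio there or for the strongest 2524 peaks, since no background window held it. Ratios that turned direction were 0.333 for Su(Hw) with windows of 50 bp to either side, and 1.17 for Dorsal and 0.812 for Grainyhead on the higher-coordinate flank. Against shuffled windows they were 2.05 for Dorsal, 1.17 for Caudal, 1.28 for the TATA box, 0.919 for Runt and 1.18 for the homeodomain core. For the strongest 2524 peaks they were 1.1 for Dorsal, 0.667 for Su(Hw) and 0.972 for Runt. Against lower-ranked pooled peaks they were 1.01 for Bicoid, 1.16 for Dorsal, 1.06 for Hunchback, 0.879 for Ohler 6, 0.344 for Su(Hw), 0.690 for CTCF and 0.669 for Grainyhead. Without 1 replicate the ratio was 1.02 to 1.06 for Dorsal, 0.935 to 1.03 for Ohler 6 and 0.750 to 1.25 for Su(Hw).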

Other observations

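Some developmental regulators were the nearest gene of many IDR summits, a count made after the data were seen, with no test and no allowance for the spacing of genes. Antp and tna were the nearest gene of 16 summits each, jing and ush of 15 each, and InR, ftz and hth of 14 each. Tom, at a complex of Notch pathway genes, and shn, a nuclear effector of Dpp signalling, had 13 each, and the Hox genes Ubx and abd-A had 12 each. The Hox gene abd-A was thus the nearest gene of 12 summits, at any distance, with none within 1000 bp of its TSSs.

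Of all 8192 sequences of 7 bases, counted after the data were seen, 837 passed as more frequent at summits than 1000 bp away and 919 as less frequent (exact McNemar test, adjusted p under 0.05). Many of the strongest outside the 23 fixed motifs resembled interrupted GA or CA repeats, such as CTCGCTC (9.05% of windows against 3.01%) and CACGCAC (9.67% against 3.39%). Those less like such repeats included TGTGCAA (10.7% of windows against 3.82%), GATAAGC, a GATA-type sequence (6.67% against 2.59%), and ATTGCGC (5.43% against 1.74%). GCAGGTA, which overlaps the Zelda consensus, was present in 5.39% against 1.35%.

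The tests of extra copies of the Mabi locus and of housekeeping genes were chosen only after the results were seen. Matched gene lists and shuffled windows were fixed before the data were examined, but the bounds for reading the matched lists were set after their result was seen. The tests among genes with a pooled peak of any rank and without long CA tracts were added after the data were seen, with bounds set before their own results. The series held 1 group, so no biological explanation was set by the design, and none was tested apart from that of housekeeping genes.

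The strongest peak lay at Mabi itself, and extra copies of the locus carried by the transgene may raise the signal there. Outside that peak's interval, 10 IDR summits lay within 10 kb, against a median of 3 around 97 other strong summits and a 95th percentile of 8.4. The count thus passed the 95th percentile, the bound set for extra copies after the results were seen, though 5 of those 97 had as many or more. By distance from the strongest summit, IDR peaks numbered 4 within 5 kb with that interval's own 2 summits included, 8 from 5 to 10 kb and 1 from 10 to 20 kb, among 8, 12 and 12 pooled peaks. The median signal of those pooled peaks was 232, 394 and 129, and 114 and 110 farther out. These medians were not compared with those around other strong summits. Binding of Mabi at its own promoter stays open, since the extent of the transgene and its copy number are not given in the sources used here.

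Early patterning genes and chromatin regulators had many promoter peaks, and gene length or number of TSSs could have produced this. Against matched random lists, 9 of the 10 lists stayed past the threshold, which argues against the matched classes of gene length and TSS number as the whole cause. Genes with many TSSs shared a class, as did the longest genes. Differences in length or TSS number within a class were not matched and stay open. Among genes with a pooled peak of any rank, 10 of 10 stayed. The IDR peaks are the strongest pooled peaks, so every gene with an IDR promoter peak stayed in that comparison. It shows that genes of these lists more often had a peak among the strongest than other genes with any pooled peak. It cannot decide on a general occupancy of genes with any ChIP signal, which could itself give strong peaks. The ratios were lower there, at 2.65 in place of 4.68 for gap and terminal genes and 2.21 in place of 3.78 for dorsoventral genes. A general occupancy thus stays open as a cause. Binding at regions open to many factors was not tested with data on other factors, and stays open, as does regulation of these genes by Mabi.

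The Zelda, GAGA and CA repeat sequences were enriched at summits, and base composition could produce such a difference. Against windows with shuffled bases and kept dinucleotides, the ratios were 3.91 for Zelda, 4.64 for GAGA and 4.42 for CA repeats. This argues against base and dinucleotide content alone as the cause. The windows 1000 bp away also exceeded the shuffled summit windows, with 3.23% against 2.59% for Zelda, 3.82% against 2.38% for GAGA and 7.35% against 4.32% for CA repeats. Part of each ratio is therefore not particular to summits, and a general richness of summits in simple repeats stays open. Leaving out peaks with 6 or more CA units in a row left 4753 peaks and a ratio of 2.47 (15.1% against 6.10%), which argues against long CA tracts. A direct contact of Mabi with any of these sequences was not tested, and binding beside other proteins that recognise them stays open.

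Ribosomal protein genes had more promoter peaks than other genes, which might belong to a general excess at short, heavily transcribed housekeeping genes. Mitochondrial ribosomal protein and proteasome genes together had a promoter peak at 24 of 121 (19.8%, ratio 1.08, Fisher's exact test, p = 0.639). The parts went opposite ways, with 24.7% for mitochondrial ribosomal protein genes (ratio 1.34, 2.73 against matched random lists with adjusted permutation p = 0.000675, and 0.956 among genes with a pooled peak of any rank) and 12.5% for proteasome genes (ratio 0.680, and 0.971 against matched lists). A general excess of housekeeping genes and one special to ribosomal protein genes cannot be told apart from these values, since the joint ratio lies between the bounds set for each and the parts differ in direction. Transcription was not measured here either, and the proteasome list includes the testis gene Prosalpha6T, with its peak beside Mabi.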
